A study of Homo sapiens with 6 samples.

How the data were processed

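Messenger RNA of 6 libraries of human lymphoid cell lines was measured by RNA-seq, with 1 library per line or condition. Of these, 4 libraries, counted here as replicates of a mantle cell lymphoma group, came from the lines JeKo-1, UPN1, Granta-519 and Z-138. The other 2 libraries came from JVM-13, a leukaemic lymphoid line, transduced with an empty vector or with a vector for cyclin D1 carrying the T286A substitution. Total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols. TopHat2 version 2.0.9, Bowtie, edgeR and the GRCh37 build are named without roles, per the submitters' processing notes. The counting program, transcript set version, strand setting and handling of reads with several matches are not given in the sources used here.

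The authors deposited RPKM values (reads per kilobase and library total) for RefSeq transcripts, 1 table per library. RPKM is the unit named per the file headers of 5 tables, and the JeKo-1 table has the same layout with no header. The low values of each table are whole multiples of what 1 read is worth, which gave the total number of reads behind each deposited RPKM table. These totals were 105848793 for JeKo-1, 98295449 for UPN1, 76838918 for Granta-519, 94837022 for Z-138, 58984654 for JVM-13 with the empty vector and 183576044 for JVM-13 with cyclin D1. These totals exceed what the MiSeq instrument named in the series design usually gives, so they may count alignments, for which the counting intervals would be too narrow. In the JVM-13 tables, RPKM times the whole span from transcript start to end gave whole reads for 100% and 99.995% of rows, within an absolute tolerance of 0.001 or a relative tolerance of 1e-06 reads. The authors' JVM-13 RPKM therefore divides by the whole span, introns included. In the 4 lymphoma tables the same product was whole in 16.1% to 19.0% of rows, and the values fitted whole reads over a shorter length. Such a length was found for 100% of the 11197 genes with a mean RPKM of at least 1 and taken as the exonic length. Where all reads of a gene share a factor with the true length, the length found is only a divisor of it. Reads recovered for such a gene are too few, and JVM-13 values placed over that length are too high.

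The JVM-13 tables also counted reads in introns and on either strand. A transcript nested inside another never had more reads than its host, in 522 of 522 same-strand and 176 of 176 opposite-strand pairs of the empty vector table, and in 1216 of 1216 and 629 of 629 pairs of the cyclin D1 table, with at least 20 reads in the nested transcript. Overlapping and antisense genes cannot be told apart in these 2 tables. The empty vector table listed 38188 coding rows and no non-coding row, the cyclin D1 one 36935 and 8205, and each of the lymphoma lines 38728 and 10806. RefSeq identifiers were given symbols from a RefSeq gene table and GENCODE metadata, used for names only, for 97.5% to 99.0% of rows. Coordinates are those of the deposited tables in GRCh37, written 1-based.

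Each gene was represented by its coding transcript of longest span. The JVM-13 pair used the 31941 rows with identical coordinates in both tables, which gave 17401 genes, and the lymphoma lines used 19011 genes. Values were compared as log2(RPKM + 1) with a mean RPKM of at least 1 over the compared libraries, and folds on this scale understate changes of low genes. The design planned limma and a camera gene set test for the lymphoma lines against JVM-13. These were not run, because the lengths behind the deposited values differ between the tables and a test would measure that difference. JVM-13 reads were instead placed over the exonic length recovered from the lymphoma tables. Intronic reads can then only raise a JVM-13 value, so genes lower in JVM-13 were counted among all genes, and genes higher in JVM-13 only among compact genes, whose span is at most 2 times the exonic length. With 1 library per JVM-13 condition and per line, no p-value was computed. Genes of the JVM-13 pair were counted at 2-fold or more. Genes of a lymphoma line were counted at 4-fold or more from the nearest of the other lines, and the same limit was used beside JVM-13.

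The median log2 ratio of each of 31 fixed gene lists was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, with at least 5 measured genes. A percentile above 97.5 or below 2.5 describes these libraries and is no test of conditions. Intervals for reads and read ratios are exact 95% Poisson and Clopper-Pearson intervals, and 3 reads were taken as the limit that 0 reads allows. Intervals and limits cover counting error only, since PCR copies were not marked. RPKM is relative to the library total, so a change shared by all genes cannot be seen in these values.

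The groups, thresholds, gene lists and rules for named genes were fixed before the data were examined. The rule named CCND1 and 9 further genes in every library, the 12 highest and 12 lowest ratios of the JVM-13 pair apart from CCND1 with an RPKM of at least 5 in 1 library, the 4 highest and 3 lowest genes of each lymphoma line with that RPKM in 1 line, and the members of each list with the largest differences, up to 4 per list. Beside JVM-13, where no test was run, the rule's fallback named 5 genes per direction. Genes on the Y chromosome, unnamed loci and symbols that end in P and a digit were not named as leading genes, so AEBP1, low in JVM-13 beside the lines, was passed over. Some of these genes and 1 list, which stay in all counts, are not reported here. Tables of other pseudocounts, filters, scalings, transcripts, length trends and left-out lines were computed as alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

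The scripts were tested on simulated data. All 4 simulated read totals of the lymphoma lines and 96.8% of 4915 exonic lengths were recovered. For the JVM-13 pair, 100% of 50 genes raised 4-fold and 52% of 50 genes lowered by the same factor were called, with 0 calls among 5452 unchanged genes. Of 20 shifted lists 18 passed the 97.5th percentile, and 1 of 20 unshifted lists fell outside the middle 95%. For the lymphoma lines, 100% of 200 raised genes and 0 of 10993 unchanged genes were called. Reads of both gene simulations were drawn with counting error only, without differences between libraries. The 0 calls among unchanged genes therefore give no rate of false calls for the real libraries.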

Results

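The series measured gene expression in 4 mantle cell lymphoma lines, a B cell lymphoma in which a translocation places CCND1 under immunoglobulin control, and in JVM-13 cells transduced with cyclin D1 T286A or an empty vector. T286A removes the threonine whose phosphorylation leads to nuclear export and degradation of cyclin D1. The series asks how cyclin D1 goes with the transcription output of malignant lymphoid cells. Each line or condition had 1 library, of 76838918 to 105848793 reads or alignments, called reads below, in the lymphoma lines, 58984654 in JVM-13 with the empty vector and 183576044 in JVM-13 with cyclin D1. There were no replicates within a line or condition, and means ± SD below run over the 4 lines.

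CCND1, which encodes cyclin D1, was high in all 4 lymphoma lines and near the detection limit in JVM-13 with the empty vector. The gene (NM_053056, chromosome 11, 69455873 to 69469242) had an RPKM of 198 in JeKo-1, 499 in UPN1, 527 in Granta-519 and 443 in Z-138, a mean of 417 ± 150 (SD, n = 4). In JVM-13 it had 22 reads with the empty vector and 32255 with cyclin D1 T286A, a deposited RPKM of 0.028 (95% interval 0.017 to 0.042) against 13.1 (13.0 to 13.3). The ratio was 471-fold (311 to 752). Over the exonic length, the scale of the lymphoma tables, the JVM-13 values were 0.087 and 41.0, so the transduced line stayed below JeKo-1, the lowest lymphoma line. A vector copy without untranslated parts adds less RPKM than an endogenous transcript of the same abundance, and the sources used here do not give the vector's insert.

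The other D-type cyclins were distributed differently. CCND2 had a mean RPKM of 0.14 ± 0.19 (SD, n = 4) in the lymphoma lines and 114 over the exonic length in JVM-13 with the empty vector, against 76.5 with cyclin D1. CCND3 had 12.9 ± 4.17 (SD, n = 4) in the lymphoma lines and 27.1 and 16.2 in the JVM-13 libraries. The CCND2 transcript spans 31621 bp over an exonic length of 3261 bp, and that of CCND3 113962 bp over 2082 bp. Neither is compact, so intronic reads may raise their JVM-13 values. SOX11, a transcription factor typical of mantle cell lymphoma, lay between 5.86 and 10.7 in the 4 lines and had 0 reads in both JVM-13 libraries, where 3 reads would have been an RPKM of 0.0058 and 0.0019. CDKN2A, the locus of p16, was measured on its transcript of longest span, which does not measure p16 separately. It had an RPKM of 80.2 in UPN1, 25.6 in JeKo-1, 0.055 from 6 reads in Z-138 and 0 reads in Granta-519, where 3 reads would have been 0.034. BCL2, an inhibitor of apoptosis, ranged from 0.088 in UPN1 to 76.6 in Granta-519, and BIRC3, a regulator of NF-kB, from 0.11 in UPN1 to 21.6 in Z-138. MYC ranged from 14.0 in UPN1 to 248 in Z-138, and ATM from 4.85 in Z-138 to 28.0 in JeKo-1. Between the JVM-13 libraries, cyclin D1 over empty vector, the read ratio was 0.93 for MYC (0.91 to 0.95), 1.11 for CDKN2A (1.04 to 1.20), 1.89 for BIRC3 (1.85 to 1.93), 2.18 for BCL2 (2.13 to 2.24) and 4.74 for ATM (4.50 to 5.00). Their exonic lengths were 2366, 1151, 6912, 6492 and 13147 bp in that order. Ratios of this pair went with transcript length, as described below, and the values here are not corrected for it.

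**Figure D1:**
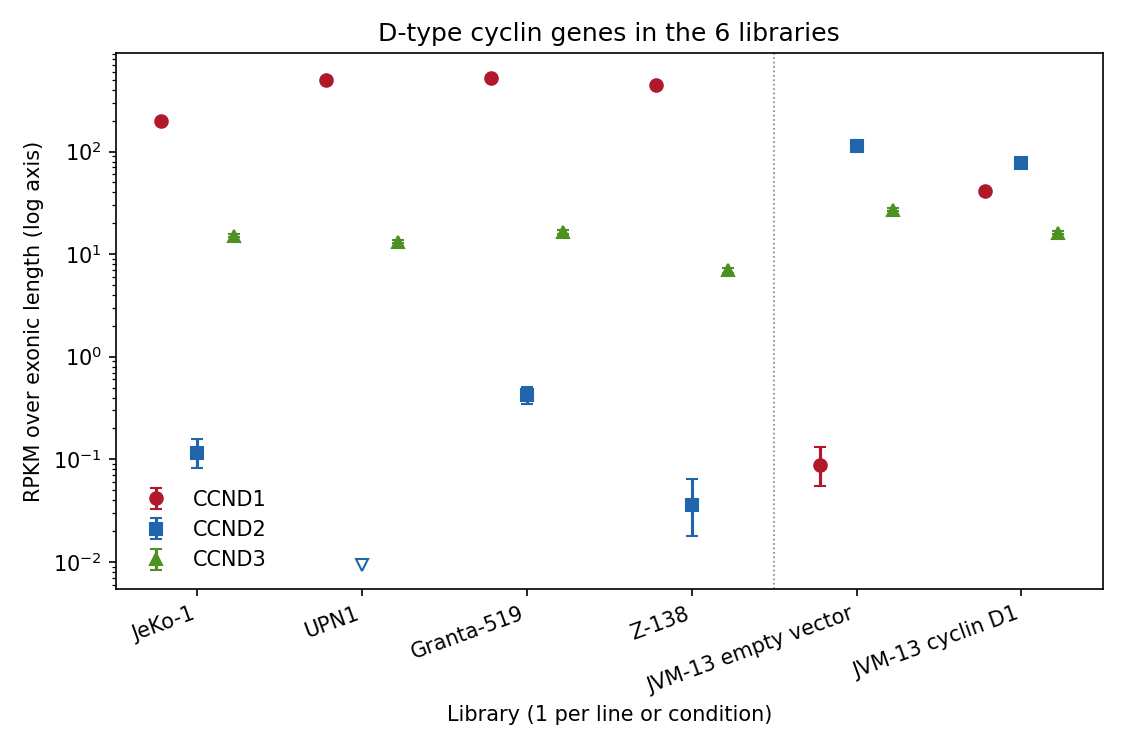
RPKM over exonic length (log axis) of CCND1, CCND2 and CCND3 in each of the 6 libraries; bars are 95% Poisson intervals of the reads, and the open triangle marks the limit of 3 reads where 0 were counted. CCND1 lay between 198 and 527 in the lymphoma lines and at 0.087 and 41.0 in the JVM-13 libraries, whose values include any intronic reads.

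The JVM-13 pair asks what differs with cyclin D1 T286A in a line with little CCND1 of its own. Interferon-stimulated genes and NF-kB targets were higher with cyclin D1 than random lists of the same expression, and mitotic, cholesterol synthesis and histone genes were lower. Of 5645 genes, 424 were at least 2-fold higher and 366 at least 2-fold lower, with a median log2 ratio of -0.06 and an SD over genes of 0.73. The balance between higher and lower genes differed between scalings. Higher genes were 53.7% of those counted with deposited values, 97.4% (4601 higher, 125 lower) after rescaling each library to the same sum of RPKM and 14.3% (204 higher, 1227 lower) after median-ratio scaling, where the median of all genes moved to 0.82 and -0.50. Rescaling also raised the values of both libraries, so that 10938 genes passed the filter and the added 1 weighed less, and its counts do not show the effect of scaling alone. Directions of lists are therefore given relative to random lists. No replicate check exists for any of these differences.

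Of the 25 lists with enough genes, 3 lay above and 3 below the middle 95% of random lists, where 1.25 lists of independent random genes would. Members of a fixed list may vary together and some lists share genes, so 1.25 is not the number due to chance for these lists. Interferon-stimulated genes had a median log2 ratio of 0.56 (percentile 100), with 6 of 24 members at least 2-fold higher and 0 lower. XAF1, a pro-apoptotic interferon target, went from an RPKM of 0.70 to 7.60, IFIT2 from 1.61 to 8.53, IFI44L from 4.26 to 15.7 and SAMD9L from 4.29 to 15.8. NF-kB targets had a median of 0.18 (percentile 99.98), which was -0.17 after median-ratio scaling, at percentile 100. TNFAIP3, an inhibitor of NF-kB, went from 14.1 to 36.9 and CFLAR from 2.92 to 7.69. The chemokine genes CCL3 (247 against 46.4) and CCL4 (a read ratio of 0.18) of the same list went the other way, so 2 of 23 members were higher and 2 lower by 2-fold.

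Mitotic genes had a median log2 ratio of -0.67 (percentile 0.02), with 8 of 24 members at least 2-fold lower. CDC20, an activator of the anaphase-promoting complex, had a read ratio of 0.34, BIRC5 went from an RPKM of 11.8 to 3.72 and PLK1, a mitotic kinase, from 12.9 to 4.19. MKI67, the proliferation marker Ki-67, was the 1 member beyond 2-fold in the other direction, at 2.95 with the empty vector and 17.0 with cyclin D1. Cholesterol synthesis genes had a median of -0.54 (percentile 0.01), with 3 of 19 at least 2-fold lower: DHCR7 (10.3 against 2.46), EBP (9.38 against 3.78) and MSMO1 (5.64 against 2.08). With a mean RPKM of at least 5 that list kept 7 genes and lay at percentile 3.1. Replication-dependent histones had a median of -0.74 (percentile 0.51), with H2AC11 (16.3 against 1.77) and H1-2 (571 against 109) among the lowest. Their percentile was 7.41 among lists matched also on gene span, 92.2 after removing the trend on span, where the median turned to 0.19, and 35.5 after removing the trend on exonic length.

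The other 19 lists lay inside the middle 95% of random lists matched on expression. Ribosomal protein genes had a median log2 ratio of -0.95 (percentile 10.5, and 0.495 matched also on span), with 56 of 57 below 0, and 23 of 57, among them RPS2 (1261 against 365), were at least 2-fold lower. Nuclear genes of oxidative phosphorylation had -0.67 (percentile 2.92, and 1.63 matched also on span), with 28 of 28 below 0 and 6 of them at least 2-fold lower. After removing the trend on exonic length the percentiles of the ribosomal and oxidative phosphorylation lists were 56.8 and 43.8, so their place depends on how length is treated. E2F and S phase genes, the targets of the pathway that cyclin D1 activates, had -0.41 (percentile 12.8), with TK1 (13.4 against 3.96), CDT1 (14.4 against 5.01) and MCM5 (15.7 against 7.13) at least 2-fold lower. The cyclin D-CDK-RB axis had -0.11 (percentile 42.9), RNA polymerase II transcription and elongation -0.05 (69.6), MYC and ribosome biogenesis -0.10 (89.3), DNA damage signalling and repair -0.09 (31), and the BCL2 family -0.03 (72.8). B cell identity genes had -0.23 (percentile 74.0), with CD79A, a part of the B cell receptor, at 104 against 34.4. MHC class II had -0.45 (47.1), MHC class I and antigen processing -0.16 (97.1), plasma cell markers -0.76 (8.25), the unfolded protein response -0.33 (72.8), glycolysis and hypoxia -0.56 (18.3), immediate early genes -0.10 (82.0), homing and adhesion -0.46 (14.1), SOX11-associated genes -0.47 (2.97), genes altered in mantle cell lymphoma 0.15 (89.1) and housekeeping genes -0.60 (19.4). EGR2 (4.77 against 0.30) and EGR1 (5.19 against 0.64), early response transcription factors, were lower, and KMT2D, a histone methyltransferase mutated in this lymphoma, was higher (0.76 against 5.68). Lists of immunoglobulin, T and NK cell, myeloid, erythroid, stromal and mitochondrially encoded genes had 3, 1, 3, 0, 1 and 0 measured genes and were not ranked. LYZ, a myeloid gene, had an RPKM of 0.23 with the empty vector and 3.21 with cyclin D1, and CD68 1.15 and 3.99. S100A9, the remaining measured myeloid gene, went the other way with a log2 ratio of -0.35.

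**Figure D2:**
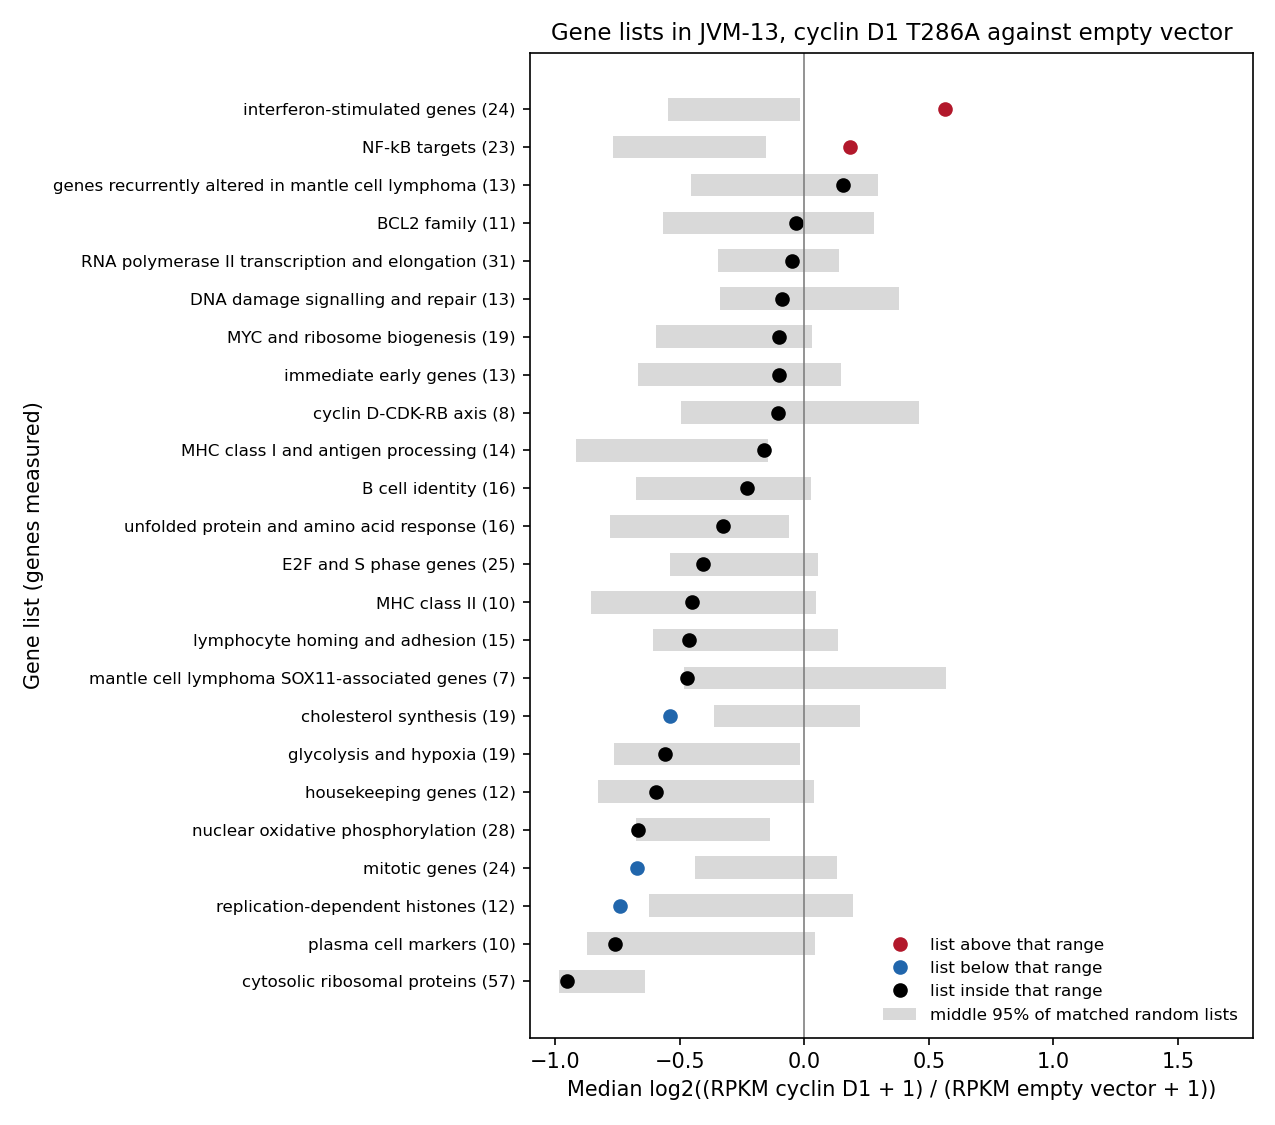
Median log2 ratio of each gene list, JVM-13 cyclin D1 T286A over empty vector (x axis, deposited values); grey bars are the middle 95% of 10000 matched random lists, and the number of measured genes follows each name. Interferon-stimulated genes lay farthest right at 0.56, and the median of NF-kB targets turned negative after median-ratio scaling.

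Apart from CCND1, most of the 12 highest genes that the naming rule allowed belong to families of near-identical copies, whose reads cannot be placed with certainty. GOLGA8A (chromosome 15, 34671270 to 34682001) had 572 reads with the empty vector and 170396 with cyclin D1, a 95.7-fold ratio (88.2 to 104), and GOLGA8B a 100.5-fold ratio (91.9 to 110). IGLL1, a surrogate light chain gene near the lambda locus (chromosome 22, 23915313 to 23922495), had 4 and 54961 reads. MTRNR2L4, UQCRHL, PPIAL4A, PPIAL4C, PPIAL4D, PPIAL4F, NPIPB3 and NPIPB5 had ratios from 14.7-fold for NPIPB3 to 643-fold for MTRNR2L4, the latter from 3 reads. PPIAL4D and PPIAL4F were listed on the same coordinates and share their 7 and 2700 reads. PPIAL4A and PPIAL4C likewise share their 18 and 1693 reads. HSPA6, an inducible heat shock gene (chromosome 1, 161494036 to 161496687), was 88.2-fold higher (61.7 to 131). Among genes chosen after their values were seen, HSPA1A (22.6 against 117), SRRM2 (9.07 against 48.7), PNN (8.46 against 49.8), OGT (9.17-fold) and NKTR (0.37 against 6.27) were also higher with cyclin D1. The 12 lowest were led by UNC45B (chromosome 17, 33474836 to 33516364), at an RPKM of 22.7 against 1.62, and included the histone genes H2AC11, H2AC18, H2AC19, H4C9 and H1-2. HFM1 (20.1 against 2.56), TMEM160 (9.78 against 1.03), CCDC85B (45.5 against 7.85), TRAPPC5 (24.6 against 3.92), CCL3 and CCL4 completed them. UNC45B spans 41529 bp and HFM1 144104 bp. Since introns and either strand were counted, their reads may come from other sequences within these spans and need not measure their transcripts. H2AC18 and H2AC19 were listed on the same coordinates and share their 5891 and 3080 reads.

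The ratio also went with gene length. Over 10 groups of the 5645 genes ordered by span, the median log2 ratio went from -0.55 at a median span of 2126 bp to 0.19 at 69474 bp. Ratios of single genes given above, among them those of ATM, BCL2, MKI67 and KMT2D, were not corrected for this trend. After removing the trend on exonic length, 389 genes were higher and 149 lower, and the lists of interferon, NF-kB, mitotic and cholesterol genes kept their side of the random lists.

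**Figure D3:**
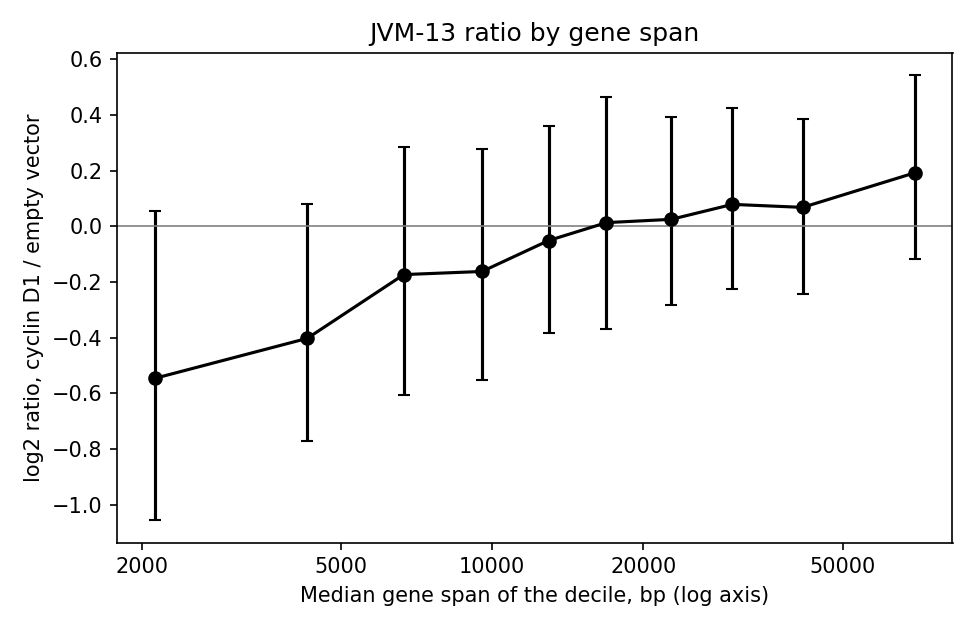
Median log2 ratio, JVM-13 cyclin D1 T286A over empty vector, for 10 groups of the genes ordered by span (x axis, median span in bp, log axis); bars run from the 25th to the 75th percentile of genes. The median rises from -0.55 to 0.19 with deposited values.

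The lymphoma lines among each other show which programmes vary beside a shared high CCND1. Granta-519 stood apart with high NF-kB targets, homing and adhesion genes and cholesterol synthesis genes, JeKo-1 with high histone genes, and Z-138 with low B cell identity genes. Of 11197 genes, 239 were at least 4-fold above every other line in Granta-519, 67 in JeKo-1, 32 in Z-138 and 22 in UPN1. In turn 45 were at least 4-fold below in Z-138, 30 in Granta-519, 27 in JeKo-1 and 14 in UPN1. These are differences between single libraries, and leaving out a line changes which gap is measured. Without Granta-519, 105 genes were above in Z-138. Without JeKo-1, 61 were above and 83 below in UPN1, and without UPN1, 123 were above and 110 below in JeKo-1.

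In Granta-519, NF-kB targets had a median log2 difference of 2.49 from the mean of the other lines (percentile 100), and 12 of 27 were 4-fold above every other line. CCL3 had an RPKM of 478, against 5.16 in the next line, EBI3, a cytokine subunit, 48.7 against 0.065, and BCL2A1, an inhibitor of apoptosis, 41.6 against 0.080. Homing and adhesion genes had a median of 1.61 (percentile 100), while CXCR4, a chemokine receptor of the same list, was at 19.7 against at least 208 elsewhere. The BCL2 family had 1.44 (percentile 100), cholesterol synthesis 1.22 (100), MHC class I 1.19 (100) and interferon-stimulated genes 0.86 (99.98). DNA damage signalling and repair had -0.52 (percentile 0) and E2F and S phase genes -0.44 (0.03). UCHL1, a ubiquitin hydrolase (chromosome 4, 41258898 to 41270446), had 370 against 1.08, and PLVAP 69.7 against 0.10. TCL1B (0.21) and CHST15 (0.070) were among the lowest against the other lines, which had at least 33.3 and 18.1. The labels give a different growth medium for Granta-519 alone, so effects of medium and line cannot be told apart.

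In JeKo-1, replication-dependent histones had a median log2 difference of 2.26 (percentile 100), with H2BC12 at an RPKM of 188 and H2BC11 at 33.3 against 3.46 in the next line. Mitotic genes had 0.33 (percentile 100), plasma cell markers -1.54 (0) and homing and adhesion genes -0.95 (0). SDC1, a plasma cell surface marker, was at 0.13 against at least 6.95 elsewhere. The cancer-testis genes SSX4 (chromosome X, 48261524 to 48271344), SSX4B, SSX3 and SSX1 had RPKM values of 479, 475, 173 and 136 against at most 0.22 in any other line, where SSX4 and SSX4B are near-identical and their reads cannot be told apart. HBEGF (0.55), NETO2 (0.18) and CENPV (0.40) were lowest against the others.

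In UPN1, RB1, the retinoblastoma gene that cyclin D1 kinases act on (chromosome 13, 48877883 to 49056026), had an RPKM of 0.092 from 43 reads, against 41.5 to 91.8 in the other lines. CDKN2C, an inhibitor of those kinases, and its neighbour FAF1 on chromosome 1 had 0 reads, against at least 12.3 and 18.7. Histones had a median log2 difference of -1.24 (percentile 0) and NF-kB targets -1.34 (0), which were -0.55 and -0.33 at their smallest among the alternatives. The NF-kB medians of JeKo-1 and Z-138, -1.01 and -0.56 with all lines, turned to 0.04 and 0.45 without Granta-519. Ribosomal protein genes had 0.52 (percentile 100), at percentile 96.2 after quantile normalization. FOXR1 (33.9 against 0.068), IMPACT, OSBPL1A and MYL4 (47.7 against 5.81) were highest.

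In Z-138, B cell identity genes had a median log2 difference of -1.09 (percentile 0), and TCL1A, a B cell oncogene, had an RPKM of 0.030 from 4 reads, against 49.6 to 633 elsewhere. Plasma cell markers had 0.66 (percentile 99.98) and left the high side without JeKo-1. Cholesterol synthesis had -0.82 (percentile 0), interferon-stimulated genes -0.67 (0.14) and the unfolded protein response 0.57 (100). At their smallest among the alternatives these medians were -0.40, -0.38 and 0.44. JCHAIN, the joining chain of secreted antibodies, was at 1374 against at most 296. DRICH1, GGTLC2, ZNF280A and ZNF280B, all on chromosome 22 between 22838772 and 23974508, were highest at 191, 289, 83.6 and 63.4, while GTSF1 (0 reads) and ALOX5 (0.041) were lowest. Over all lines 30 combinations of list and line lay above and 28 below the middle 95% of random lists. Of 108 combinations, 5.4 would for independent random genes, which is not the number due to chance for lists whose members may vary together. The 4 lines also share 1 set of differences, so the combinations are not independent. Of the 58, 24 kept their side in all 11 alternatives that applied.

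**Figure D4:**
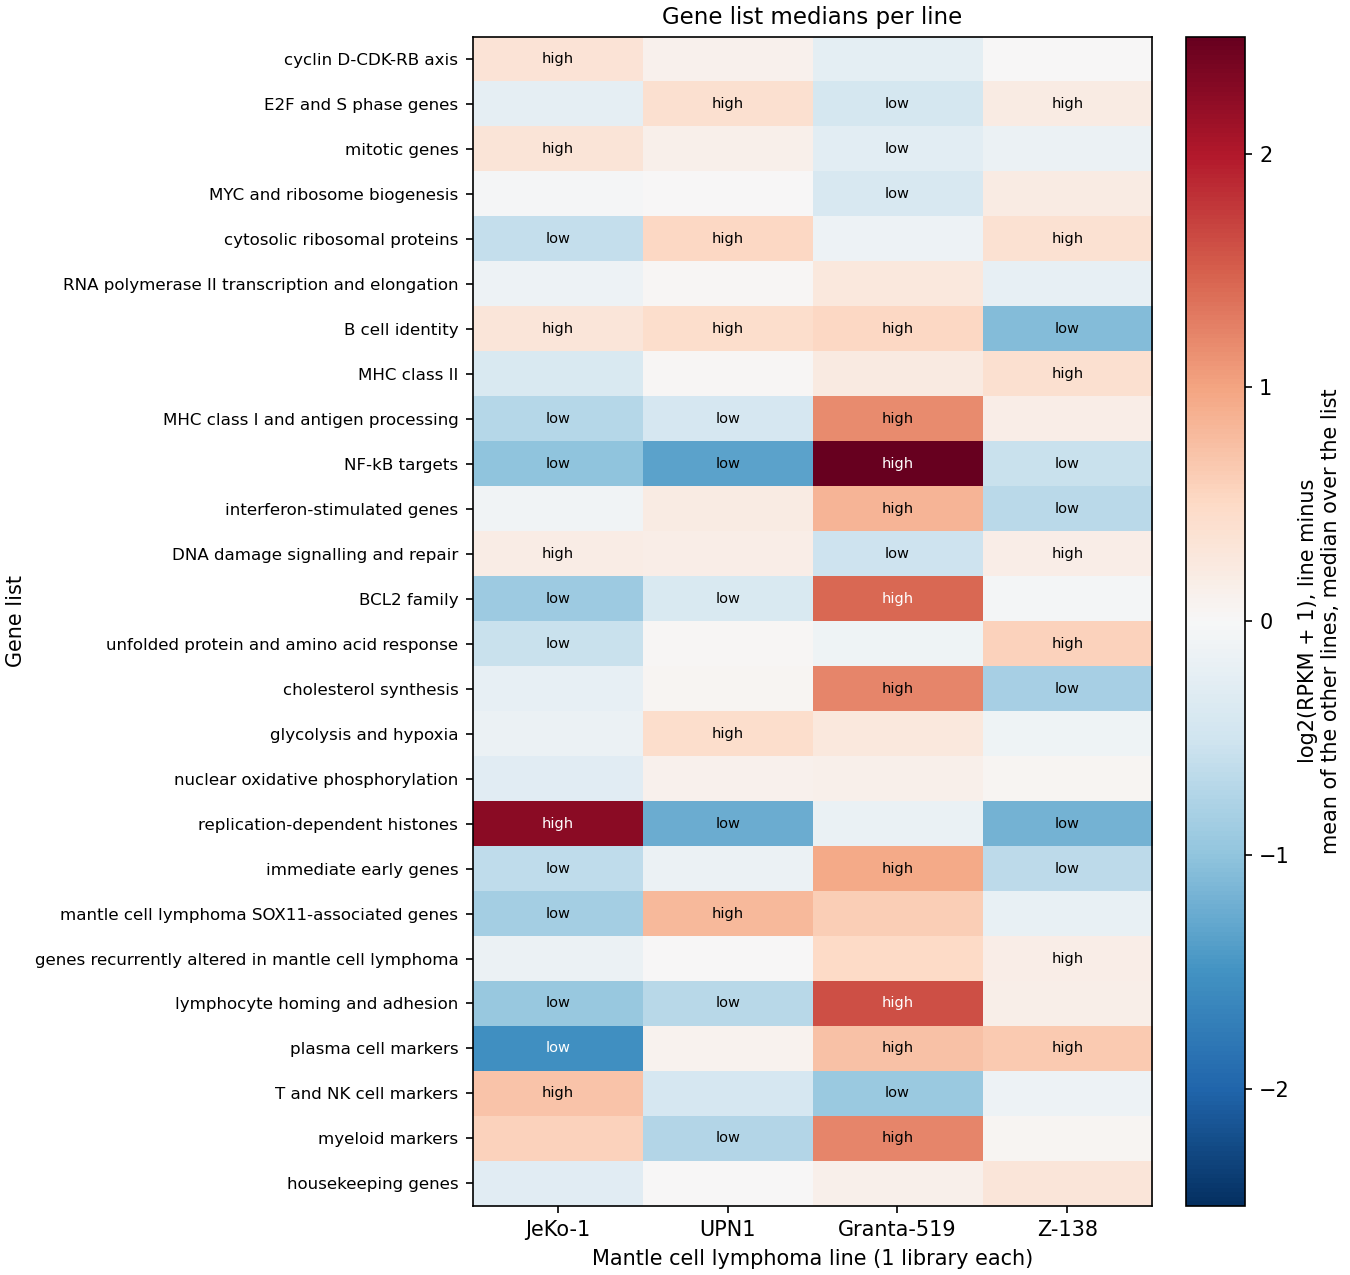
Median over each gene list (rows) of log2(RPKM + 1) in a lymphoma line (columns) minus the mean of the other lines, in colour; "high" and "low" mark medians outside the middle 95% of 10000 matched random lists. NF-kB targets in Granta-519 (2.49) and histones in JeKo-1 (2.26) are the strongest colours.

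Set beside the lymphoma lines, JVM-13 with the empty vector had no SOX11 reads, little CCND1 and CD72 and less of 3 of 12 MHC class II genes, and more LTA, GPR15 and interferon-induced IFITM1 and ISG15. The tables were normalized separately, so these are sizes with no test. Of 10314 genes, 49 were at least 4-fold lower in both JVM-13 libraries than in each line, and 89 more in the empty vector library only. Of 699 compact genes, 13 were at least 4-fold higher, 10 of them in both JVM-13 libraries. The median log2 difference was -0.24. After CCND1, the lowest genes that the naming rule allowed were OTOA at 0.91 over the exonic length against 102 ± 35.7 (SD, n = 4), IGLL1, BZW2 at 0.68 against 81.7 ± 49.5 (SD, n = 4) and TCL1B. IGLL1 and TCL1B were also low in Granta-519 and did not pass 4-fold.

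Of 12 MHC class II members, 3 were at least 4-fold below the lines: HLA-DMB (3.29 against 61.5 ± 9.42, SD, n = 4), HLA-DOA (1.76 against 26.8 ± 1.41, SD, n = 4) and CIITA, their transactivator (3.10 against 37.0 ± 8.54, SD, n = 4). CD72, a B cell co-receptor, was at 0.85 against 54.9 ± 40.8 (SD, n = 4), and ITGB1, an integrin, at 1.60 against 37.0 ± 9.97 (SD, n = 4). KMT2D, CIITA, the mitotic genes MKI67 and CENPF and the repair genes BRCA2 and XRCC2 were at least 4-fold lower in the empty vector library only. So were NPIPB3 (10.7 with the empty vector, 157 with cyclin D1) and NPIPB5 (8.32 and 155), from the families of near-identical copies. None of these values was corrected for the trend of the JVM-13 ratio with transcript length. GPR15, a homing receptor, had 71.9 against 0.23 ± 0.22 (SD, n = 4), LTA, a cytokine of the TNF family, 97.9 against 2.73 ± 5.37 (SD, n = 4), IFITM1 387 against 19.8 ± 15.9 (SD, n = 4) and ISG15 306 against 21.0 ± 13.8 (SD, n = 4). H1-2, IER3 and DDIT4 were also among the higher compact genes, and MSC (33.4 against 8.96 in Granta-519 and 0 elsewhere) did not pass 4-fold. The count of genes lower with the empty vector was 596 after rescaling to the same sum and 251 without Granta-519.

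At an RPKM of at least 1, 10879 of 19011 genes were detected in JeKo-1, 10693 in UPN1, 11025 in Granta-519 and 10503 in Z-138. In JVM-13, 5057 of 17401 were detected with the empty vector and 6062 with cyclin D1 on the whole-span scale, which is not comparable with the lines. The 10 highest genes, led by ACTB, EEF1A1 and TMSB4X with the empty vector, held 19.2% of summed RPKM there and 13.1% with cyclin D1. In the lymphoma lines, on the exonic scale, the 10 highest held 6.76% to 8.54%, which cannot be set against the JVM-13 shares. At an RPKM of at least 5 the order of the JVM-13 libraries turned, with 1927 and 1740 genes. A relation of CCND1 with total RNA over 4 lines was not tested, since RPKM holds no total RNA and 4 lines are too few.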

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

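The test of genomic DNA reads was chosen after the result was seen, and the other tests of this part were chosen before. In 39 sets of values over the 4 lymphoma lines, 2 lines lay far from the others, which is about the 1 in 20 that chance gives. For B cell identity genes, the median log2(RPKM + 1) was 4.16 in Z-138 against 5.67 to 5.92 in the other lines, a gap of 0.857 of the whole range. For immediate early genes it was 3.80 in Granta-519 against at most 2.71, a gap of 0.842 of the range. In the cyclin D1 table of JVM-13, 122 small non-coding rows under 200 bp, which no comparison used, had an RPKM of at least 100. SNORD42B had 1817, and the lymphoma tables had 171 to 210 such rows.

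The ratio of cyclin D1 to empty vector in JVM-13 went up with gene span. Genomic DNA reads were argued against, since 371 olfactory receptor genes gained an RPKM of 0.063 (95% bootstrap interval 0.028 to 0.11) where the 108 genes over 100 kb gained a median of 0.43. A larger intronic share was argued against by the partial rank correlation over 5448 genes with intronic length at fixed exonic length and mean RPKM, -0.10 (-0.13 to -0.07). The slope of the ratio on log10 span was 0.38 after thinning the cyclin D1 reads to the empty vector total and 0.39 before. Thinning keeps each expected RPKM, so it shows only that counting noise does not make the trend. Other effects of depth were not tested. A lower yield of short transcripts in the cyclin D1 library may account for the trend. The partial rank correlation with exonic length, at fixed intronic length and mean RPKM, was 0.38 (0.36 to 0.41). For 215 single-exon genes the plain rank correlation of the ratio with their length, with nothing held fixed, was 0.23 (0.10 to 0.37). A ratio cannot show which library is off, so a lower yield of long transcripts in the empty vector library would give the same values. An effect of cyclin D1 T286A on long and short genes cannot be told apart from either, with 1 library per condition.

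Genes annotated at more than 1 locus had a median log2 ratio of 0.23, against -0.06 for the rest, and of 53 such genes 20 were at least 2-fold higher and 6 lower. Some of them, such as PPIAL4D and PPIAL4F or H2AC18 and H2AC19, share coordinates and reads, so these counts hold some measurements more than once. Dropping of reads with several matches from the empty vector table alone was argued against for transcripts annotated at several loci. Of 1164 such transcripts, 28.6% had fewer than 3 reads in the empty vector table and 28.2% in the thinned cyclin D1 reads. The difference was 0.43 percentage points (-1.72 to 2.49), while single-locus transcripts had 17.1% and 10.1%. Copies with names of their own, such as GOLGA8A, GOLGA8B, NPIPB3 and NPIPB5, are annotated at 1 locus and were not covered. For them, dropping of such reads stays open. The median after thinning was 0.20. Since thinning keeps each expected RPKM, this value does not decide whether depth plays a part beyond counting noise. Other ways of sharing reads between copies, and a biological difference, stay open and were not tested.

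Replication-dependent histone genes were low with cyclin D1 in JVM-13, at percentile 0.51 of random lists. Their short span may account for this, since they lay at percentile 7.41, inside the middle 95%, among lists matched on expression and span. Fewer cells in S phase would also lower the E2F and S phase list, whose percentile of 12.8 lies neither among the lowest 2.5% nor above the middle, so this stays open.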

How the results depend on the processing

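No paired analysis was possible because each JVM-13 condition has 1 library and the replicate numbers of the lymphoma lines were given in accession order. The planned limma fits (trend, no trend, robust) and camera tests were not run, as the tables rest on different lengths. Length trends, single-locus and compact genes, other transcripts, whole-span values and the lists per line were chosen after seeing the data. Of the main results, 91 values under alternatives stayed within their limits and 46 moved, and of named genes 520 stayed and 68 moved, mostly with the pseudocount.

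For JVM-13 (424 higher, 366 lower), a pseudocount of 0.1 gave 765 higher and 5 gave 66 and 174. A mean RPKM of at least 5 gave 74 higher, rescaling to the same sum 4601 and 125 of 10938, where more genes passed the filter and the pseudocount weighed less, median-ratio scaling 204 and 1227, and quantile normalization 190 lower. Removing the trend on span gave 150 lower, that on exonic length 149, and compact genes alone 94 and 90 of 643, where fewer genes were compared. Lists above the random range numbered 5 with a mean of at least 5, and those below 5 after rescaling and after quantile normalization. Interferon, NF-kB and mitotic genes kept their side in all 11 alternatives, cholesterol synthesis in 10 and histones in 9, though the NF-kB median turned from 0.18 to -0.17 after median-ratio scaling and the histone median from -0.74 to 0.19 after removing the span trend.

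For the lymphoma lines (360 above, 116 below), a pseudocount of 0.1 gave 449 below and 5 gave 124 and 26, a mean of at least 5 gave 172 above, and rescaling gave 218 below. Leaving out 1 line gave 264 to 539 above and 176 to 262 below, as a gap to 2 lines is passed more easily than to 3, and 17 to 22 lists high and 17 to 26 low, with fewer combinations. Beside JVM-13 (49 and 89 lower in both libraries and with the empty vector only, 13 compact higher), pseudocounts of 0.1 and 5 gave 467 and 29 lower, rescaling 596 and 8, median-ratio scaling 20 higher, both JVM-13 libraries 49 lower, whole-span values 4082 and 8, and leaving out 1 line 157 to 251 lower and 15 to 26 higher. The mean CCND1 of the lines was 840 after rescaling (380 to 490 with a line left out) and its JVM-13 ratio 708. JVM-13 genes detected were 1927 and 1740 at an RPKM of at least 5, and 9569 and 11441 after rescaling, with the empty vector and cyclin D1. Scaling and pseudocount act by construction; otherwise the cause was not tested. Depth limits genes with few reads, such as CCND1 with 22 in the empty vector library.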

Other observations

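All genes of this paragraph were chosen after their values were seen. In JeKo-1 the genes 4-fold above the other lines included further cancer-testis genes on chromosome X, SSX5, SSX2, SSX2B, SSX7, CTAG1A, CTAG1B, CTAG2, RHOXF2 and RHOXF2B, most of them in pairs of near-identical copies. Granta-519 had 19 protocadherin gamma genes of 1 cluster on chromosome 5 (140710252 to 140892548), which share exons so that their reads are not independent, and the metallothionein genes MT2A, MT1E, MT1G and MT1H on chromosome 16. Genes 4-fold above the other lines lay within 1 Mb of each other in 329 pairs in Granta-519, where the middle 95% of random draws reached 65, in 37 pairs in JeKo-1, where it reached 8, in 4 pairs in Z-138, where it reached 2, and in 1 pair in UPN1, where it reached 2. The protocadherin cluster alone accounts for many of the pairs in Granta-519.

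Genes at least 4-fold below every other lymphoma line also lay close together, and loss or silencing of chromosome segments in single lines may be a reason, a hypothesis set before the pairs were counted. Over the 4 lines, 115 such genes off the Y chromosome made 11 pairs within 1 Mb, above the 7 at which the middle 95% of 10000 random draws ended. Per line the pairs passed that level in UPN1 (2 against 1) and Granta-519 (4 against 3), and not in JeKo-1 (2 against 2) or Z-138 (3 against 5), so the prediction for each line was not met and the question stays open. Among the lines that passed, the pairs in UPN1 were FAF1 with CDKN2C and RB1 with LPAR6. LPAR6 lies within the span of RB1, so that pair is a gene and its host, and the pass of UPN1, 2 against 1, rests on it. In Granta-519 they were KLHL9 with MTAP, PHGDH with NOTCH2, SYCP2L with ELOVL2, and ANKMY2 with BZW2.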
